A study of Mus musculus with 6 samples.

How the data were processed

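Total RNA of samples described as mouse chondrocytes was sequenced in 3 control and 3 Eldr cKO libraries. Per the labels' protocols, RNA was extracted with Trizol, enriched by poly(A) selection or by removal of ribosomal RNA, made into libraries with a stranded kit and sequenced on an Illumina HiSeq instrument. Which enrichment was used for which library is not given in the sources used here. Nothing in the labels says that the libraries of a group came from separate animals or cultures. P-values therefore rest on the spread between these libraries, which may be technical.

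The authors' deposited table held 1 FPKM value per gene and library, made with cutadapt, HISAT2 2.0.5 and StringTie, per the submitters' processing notes. These notes name the human build hg19, while the gene IDs in the table are mouse. Of its 12560 rows, all protein coding per the table, 12550 had an ID in GENCODE M21 and 11621 lay within 1 bp of that annotation's position on GRCm38, so GRCm38 is the build given for coordinates. Of the group columns headed FPKM in the deposited table, the values equalled the mean of log2(FPKM + 1) over the 3 libraries of a group, computed by the authors. The deposited log2 fold change was the difference of these means, Eldr cKO minus control, and the deposited fold was its antilog. The p-value in the authors' deposited table differed by at most 9.7e-13 from that of a two-sided equal-variance test on log2(FPKM + 1). The deposited q-value did not follow from a Benjamini-Hochberg adjustment over the listed rows, which left 1 row under 0.05. Each listed row had a mean log2(FPKM + 1) of at least 0.441 in 1 group, and the rule by which the authors kept rows is not given in the sources used here. A further row was empty and is not reported here.

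Depth was estimated from the steps in FPKM. For genes with 1 annotated transcript, the inverse of FPKM times transcript length took values at the library total divided by whole numbers, and the most frequent value was taken as the total. Within a tolerance of 3%, 85, 87, 70, 135, 73 and 80 genes lay at 1 fragment in control 1, 2, 3 and Eldr cKO 1, 2, 3. At most 9 genes lay at a position short of 1 fragment. That position is not between steps, so it gives no check of them. Of 15 pairs of libraries, 14 had a most frequent between-library ratio of FPKM within 1% of that from the estimated totals, and the pair of control 1 and Eldr cKO 2 was off by 198%. Counts were not recovered for all genes, so no count model was used. At 10 FPKM, a 2 kb transcript stood on 9.29 fragments in control 1 and on 1.05 in Eldr cKO 2. Since genes used by every cell were listed at 0 in shallow libraries, a value of 0 is reported as listed at 0, and values are given per library.

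Groups, tests, gene lists and the rule for named genes were fixed before the data were examined. FPKM values were used as deposited, and a change is given on the log2(FPKM + 1) scale. This scale shrinks the change of low genes whose values lie above 0. Against a value of 0, the change made by 1 fragment is larger in a shallow library. On a 2 kb transcript 1 fragment was worth 1.08 FPKM in control 1 and 9.55 FPKM in Eldr cKO 2. Genes with a mean of at least 1 FPKM over the 6 libraries were tested with limma 3.58.1 in R 4.3.3. The test was moderated and two-sided, with an intensity trend and genotype as the single factor. P was adjusted by the Benjamini-Hochberg method with a threshold of 0.05. In the main fit the prior degrees of freedom were estimated as infinite. Each SE and p therefore came from the variance trend over genes, and a gene's own spread had no weight. Of 38 gene lists, those with at least 5 tested genes were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Named genes were 21 fixed genes, then the 10 genes higher and the 10 lower in Eldr cKO with the largest change among those past the threshold, filled by the smallest unadjusted p where fewer passed, leaving out predicted genes, and up to 4 members of each list described. Eva1b, Apopt1, Gm10800, Gm21738, Hpip, Dcn, Bgn and the heart muscle genes lay outside that rule and were chosen after their values were seen, as were 4 added lists for heart muscle, fast skeletal muscle and core cartilage genes. The heart-restricted list shared 0 genes with the cartilage list, and the list shared by heart and slow muscle held 1 gene of the skeletal muscle list.

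The limma script was tested on simulated data drawn at the estimated depths for 8991 genes, of which 200 were changed. It recovered 0.0% of 4-fold and 56.5% of 16-fold changes at these depths, and 93.5% and 100% at 100 times the depth. Alternatives were pseudocounts of 0.1 and 0.5, no filter and a minimum of 5 FPKM, quantile normalization, median centring, robust variance estimation, library quality weights, each library left out in turn, and the replicate number as a block with and without quantile normalization. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9.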

Results

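RNA sequencing libraries had been made from samples described as mouse chondrocytes, the cells that build and maintain cartilage, with 3 libraries from controls and 3 from Eldr cKO mice. Eldr is a long noncoding RNA, and the series title places it in the senescence of chondrocytes, a lasting growth arrest linked to ageing and joint injury. The comparison of both genotypes addresses which chondrocyte genes differ when Eldr is targeted. The table used here gave FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) for 12560 protein-coding genes in each library. Eldr itself had no row and was not analysed here, so the genotype labels were not checked on the targeted gene.

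The libraries were shallow and differed in content. FPKM values of weakly detected genes lay on steps worth 1 fragment, and the depth estimated from these steps was 464360, 79234 and 130370 fragments in control 1, 2 and 3 and 191540, 52354 and 55987 in Eldr cKO 1, 2 and 3. A single fragment on a 2 kb transcript was worth between 1.08 FPKM in control 1 and 9.55 FPKM in Eldr cKO 2. Values above 0 were listed for 9939, 4717 and 7832 genes in the controls and for 9239, 4601 and 4907 genes in the Eldr cKO libraries. Mitochondrial genome transcripts made up 68.0%, 70.0% and 41.1% of the summed FPKM in the controls and 43.6%, 33.9% and 33.8% in the Eldr cKO libraries. A group of 12 predicted genes in repeat-rich sequence, led by Gm10800 (GRCm38 chromosome 2, 98666547 to 98667301), made up 3.07%, 12.9% and 13.4% in the controls and 3.84%, 48.8% and 46.2% in the Eldr cKO libraries. Gm10800 alone was listed at 9208, 34447 and 26167 FPKM in the controls and at 7113, 139652 and 131405 FPKM in the Eldr cKO libraries. Pearson correlations of log2(FPKM + 1) across genes, which are not independent replicates, ranged from 0.37 to 0.51 between libraries of the same genotype and from 0.38 to 0.68 between genotypes, the highest being that of control 1 with Eldr cKO 1.

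**Figure D1:**
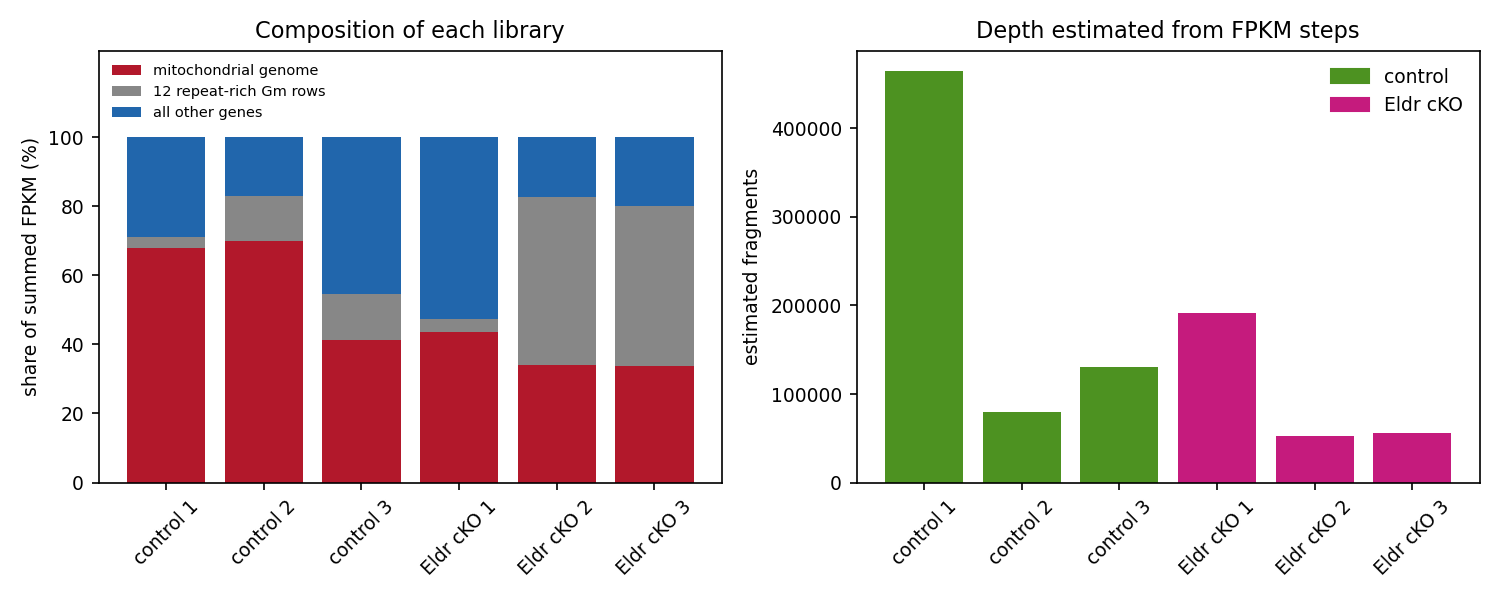
Left, share of the summed FPKM (%) of each library held by mitochondrial genome transcripts, by 12 repeat-rich predicted genes and by all other genes. Right, depth of each library in fragments, estimated from the steps in FPKM; control 1 was the deepest at 464360 fragments, and repeat-rich genes held 48.8% and 46.2% of Eldr cKO 2 and 3.

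Listed core cartilage genes were sparse in every library, and heart muscle genes were abundant in every library. Of 39 genes of cartilage matrix and chondrocyte identity, 18 had a row, while Col2a1 and Acan, which encode type II collagen and aggrecan, had none and were not analysed here. Of the 18, 17, 7 and 12 were above 0 in control 1, 2 and 3 and 13, 9 and 8 in Eldr cKO 1, 2 and 3, and 4 were above 0 in all 6 libraries. Among these 4 were Dcn and Bgn, which encode the proteoglycans decorin and biglycan of many connective tissues. Dcn was listed at 93.5, 4.32 and 78.6 FPKM in the controls and at 54.7, 15.7 and 23.8 FPKM in Eldr cKO, and Bgn ranged from 14.8 to 45.1 FPKM. Sox9, the transcription factor that drives chondrocyte identity, was listed at 0.877, 0 and 0.728 FPKM in the controls and at 1.24, 0 and 6.13 FPKM in the Eldr cKO libraries. Comp, a cartilage matrix glycoprotein, was above 0 in control 1 (0.723 FPKM) and Eldr cKO 1 (11.2 FPKM) alone. By contrast Myh6, the alpha myosin heavy chain of heart muscle, was listed at 2920, 527 and 195 FPKM in the controls and at 1758, 293 and 302 FPKM in the Eldr cKO libraries. Nppa, the atrial natriuretic peptide, was listed at 967, 427 and 93.4 FPKM in the controls and at 1289, 147 and 614 FPKM in the Eldr cKO libraries. Tnni3, cardiac troponin I, ranged from 103 to 804 FPKM, and Mb, the myoglobin of heart and skeletal muscle, from 406 to 4048 FPKM. Of 12 genes largely restricted to heart muscle, 7 were above 0 in all 6 libraries, and of 14 genes shared between heart and slow skeletal muscle, 14 were. The summed FPKM of the heart-restricted genes was 34.3, 36.3 and 4.65 times that of the listed cartilage genes in control 1, 2 and 3 and 36.0, 14.2 and 29.5 times in Eldr cKO 1, 2 and 3. Of 14 core cartilage genes 5 had a row, and 0 were above 0 in all 6 libraries. Of 12 genes of fast skeletal muscle 3 had a row, among them Myl1, a fast myosin light chain, listed at 27.2, 4.04 and 3.71 FPKM in the controls and listed at 0 in the Eldr cKO libraries. The heart, fast muscle and core cartilage lists were drawn up after the data had been seen. Between genotypes the heart-restricted list did not differ in limma's camera test (6 genes higher and 6 lower in Eldr cKO, unadjusted p = 0.740), and the shared list had 11 genes higher and 3 lower (unadjusted p = 0.0487, and p = 0.588 with an estimated correlation).

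**Figure D2:**
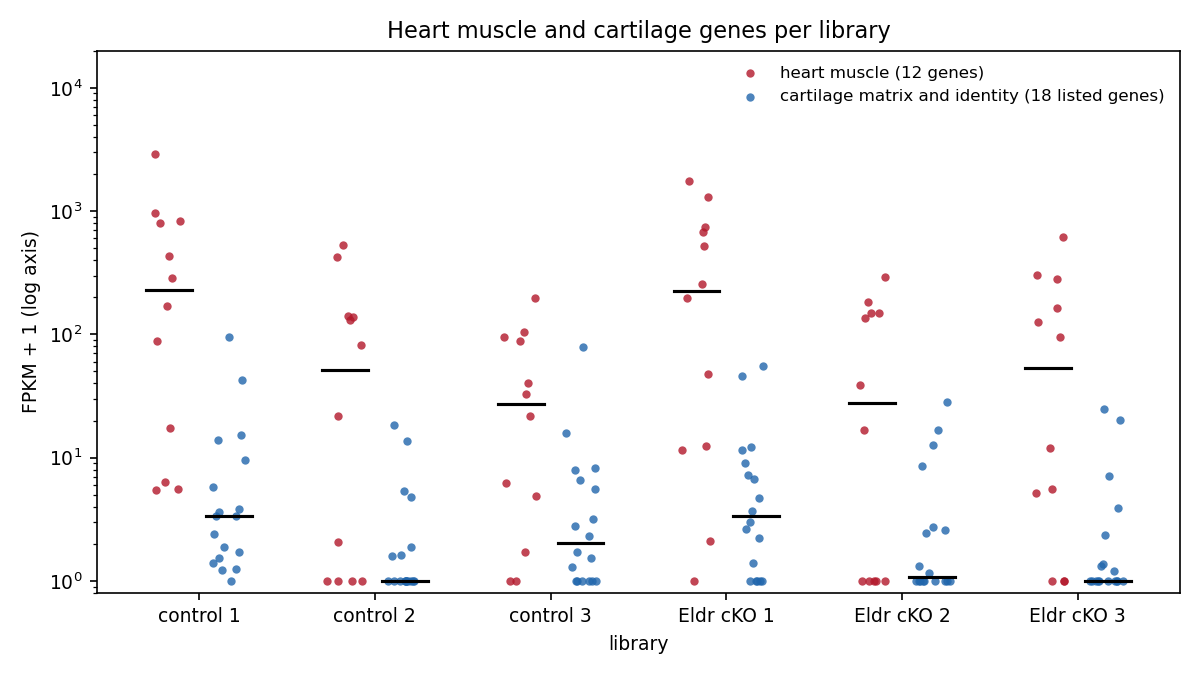
FPKM + 1 on a log axis for 12 heart muscle genes and for the 18 listed genes of cartilage matrix and chondrocyte identity in each library; each point is a gene and each bar the median over genes. Myh6 reached between 195 and 2920 FPKM, while Sox9 was at most 6.13 FPKM.

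No gene passed the test between Eldr cKO and control. Among 9007 tested genes, limma with Benjamini-Hochberg adjustment called 0 higher and 0 lower in Eldr cKO, the smallest adjusted p being 0.999. An unadjusted p under 0.05 was found for 135 genes, fewer than the 0.05 share of tested genes, a share that takes no account of values at 0. Of the 135, 41 were higher and 94 lower. Single libraries set this balance: it was 85 higher and 37 lower without Eldr cKO 2, 55 and 44 without Eldr cKO 3, 26 and 172 without control 2, and 58 and 319 without Eldr cKO 1. In simulated libraries of the estimated depths, limma recovered 0.0% of 4-fold and 56.5% of 16-fold changes. These libraries shared a common expression profile and a preset spread and left out mitochondrial genes. The result therefore holds for those settings and does not cover every gene here. The groups did not overlap for 355 genes, which is 5.08% of the 6984 genes whose values could separate 3 against 3 despite ties at 0, against 10% by chance. Dropping Eldr cKO 1 gave 4 calls (Gm10800 and Gm21738 higher, Atp5k and Atpif1 lower in Eldr cKO), and dropping control 1 gave 1 call, mt-Nd4, which encodes a subunit of respiratory complex I, higher in Eldr cKO.

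The genes with the smallest unadjusted p are named here although none passed. Atp5k, a subunit of ATP synthase (GRCm38 chromosome 5, 108433244 to 108434448), was listed at 225, 37.9 and 175 FPKM in the controls and at 101, 0 and 0 FPKM in Eldr cKO, a log2 fold change of FPKM + 1 of -4.63 (SE 1.26). Atpif1, an inhibitor of ATP synthase, had a log2 fold change of -4.40 (SE 1.28), mt-Atp6 one of -1.92 (SE 0.56) and Ndufa1, a complex I subunit, one of -3.22 (SE 1.08). Ndufa1 was listed at 391, 200 and 475 FPKM in the controls and at 149, 308 and 0 FPKM in Eldr cKO, and its log2 fold change was -0.64 without Eldr cKO 3, while that of mt-Atp6 was -0.85 without Eldr cKO 2. Atp5k and Atpif1 were listed at 0 in Eldr cKO 2 and 3, the libraries with the lowest depth and the highest repeat-rich share. Of 36 nuclear genes of oxidative phosphorylation, 17 were higher and 19 lower in Eldr cKO (camera, adjusted p = 0.949), and this list was called lower without control 3 (adjusted p = 0.0350, with a range up to 0.998 over the alternative fits). Hspe1, a mitochondrial chaperonin (-3.72, SE 1.25), Polr2k, a subunit shared by RNA polymerases (-4.04, SE 1.33), and Cfdp1 (-4.01, SE 1.31) followed, Hspe1 being at -2.26 without Eldr cKO 2. The chemokine gene Ccl8 was listed at 7.62, 24.4 and 30.1 FPKM in the controls and at 0 in each Eldr cKO library. On the higher side, Ssr2 (3.94, SE 1.37) and Tmem147 (3.72, SE 1.37) encode proteins of the endoplasmic reticulum translocon, Ecm1 (3.66, SE 1.32) an extracellular matrix protein, Psmb5 (3.59, SE 1.34) a proteasome subunit, U2af1 (3.32, SE 1.22) a splicing factor and Apoa1 (3.71, SE 1.34) the main protein of high-density lipoprotein. Ssr2, Tmem147, Psmb5 and Apoa1 were listed at 0 in control 2 and 3. In Eldr cKO 2 and 3, Ssr2, Tmem147 and Apoa1 lay between 15.5 and 20.6 FPKM. There 1 fragment on a 2 kb transcript was worth 9.55 and 8.93 FPKM, so these values may stand on few fragments. The log2 fold change of U2af1, listed at 0 in control 2, was 1.56 without that library. Irf2bpl had a log2 fold change of 3.67 (SE 1.39). For mt-Nd4 the log2 fold change was 1.69 (SE 0.65), and it was -1.39 without control 3. Control 3 was listed at 23.3 FPKM against 20601 and 10812 FPKM in the other controls, a spread that this SE does not reflect. The authors' equal-variance test gave p = 0.616 for mt-Nd4. The smallest unadjusted p on each side included rows named Foxo1 (5.08, SE 1.31) and Errγ (3.88, SE 1.37), higher in Eldr cKO, and Ihh (-4.62, SE 1.33) and Itgbl1 (-4.20, SE 1.35), lower in Eldr cKO.

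These 4 rows and a row named Hpip were the only 5 that broke the gene ID order of the table, and their identity is uncertain. The rows named Ihh and Itgbl1 lie on the strand opposite to GENCODE M21, which no other row with an ID in that annotation does, and those named Hpip, Foxo1 and Ihh lie off the GRCm38 position of their gene ID. The Hpip row carries the ID of the separate Hcfc1r1 row. All 5 had a p under 0.05 in the authors' deposited table, against 244 of the other 12555 rows (1.94%; two-sided Fisher's exact test, p = 2.94e-09). The values of these rows are given under the names the table prints.

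Regulators of senescence and cartilage turnover did not pass the test in either direction. Cdkn1a, which encodes the cell cycle inhibitor p21 (GRCm38 chromosome 17, 29090979 to 29100722), was listed at 0 in each control and at 50.2, 0 and 15.0 FPKM in Eldr cKO (limma, adjusted p = 1.00). The row named Ihh was listed at 37.0, 62.4 and 78.4 FPKM in the controls and at 11.8, 0 and 0 FPKM in Eldr cKO (limma, adjusted p = 1.00). Igfbp7, a secreted factor of senescent cells, was listed at 36.3, 0 and 19.1 FPKM in the controls and at 92.9, 30.5 and 48.1 FPKM in Eldr cKO, a log2 fold change of 2.53 (SE 1.27) that became 0.94 without control 2. The log2 fold changes of Sox9 (0.77, SE 1.25), Ptch1, the hedgehog receptor (0.74, SE 1.29), Adamts4, an aggrecan-cleaving protease (0.67, SE 1.07), Col10a1, the collagen of hypertrophic cartilage (0.60, SE 1.24), and Prg4, which encodes lubricin (-0.72, SE 1.37), were smaller than their errors. The same held for Hnrnpl (0.61, SE 1.30), Kat6a (0.13, SE 1.34) and Egfr (0.29, SE 1.25). With 1 of the libraries left out, Prg4, Kat6a, Egfr, Adamts4 and Col10a1 turned direction, the last 2 without Eldr cKO 1 (-0.24 and -0.63), and Sox9 was at 0.015 without Eldr cKO 3, Ptch1 at 0.253 without Eldr cKO 2 and Hnrnpl at 0.255 without Eldr cKO 1. Runx2, Mmp13 and Adamts5 stayed below a mean of 1 FPKM and were not tested. Cdkn2a, Cdkn2b, Gli1 and Il6 had no row and were not analysed here.

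**Figure D3:**
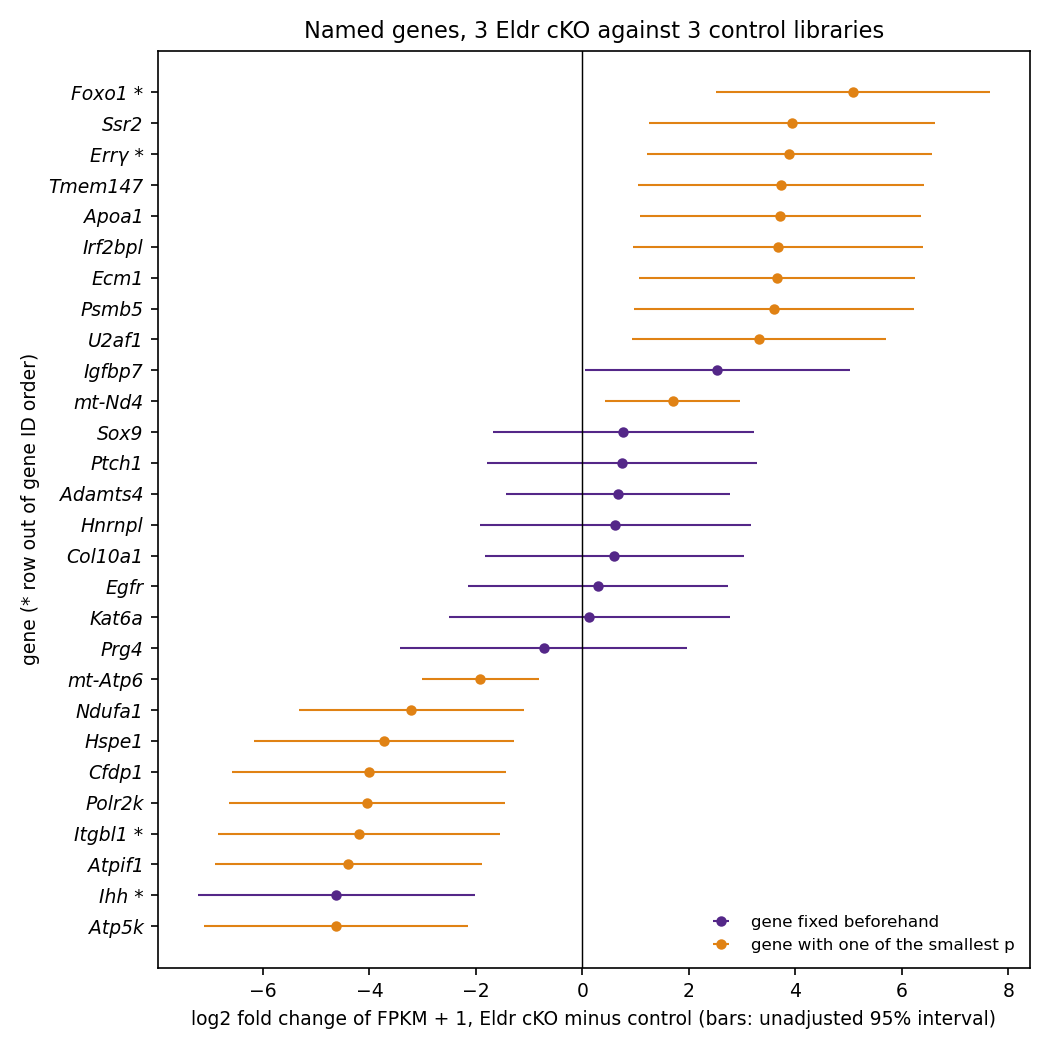
Log2 fold change of FPKM + 1 (Eldr cKO minus control, 3 libraries each) with its unadjusted 95% interval for the tested named genes. Cdkn1a and Ccl8, listed at 0 throughout a group, are left out. Interval widths come from the variance trend over genes, not from a gene's own spread. Purple points are genes fixed beforehand, orange points have one of the smallest unadjusted p, and asterisks mark rows out of gene ID order; no gene passed adjustment.

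Of 35 gene lists tested, camera with a preset correlation of 0.01 called the mitochondrial genome list down and the neutrophil marker list up in Eldr cKO. Of 13 mitochondrial genes, 12 were lower and 1, mt-Nd4, higher, with a median log2 fold change of -0.99 (limma camera, adjusted p = 1.87e-08). With an estimated correlation the adjusted p of this list was 0.980. None of the 13 passed over all genes tested, and 3 (mt-Atp6, mt-Atp8 and mt-Nd4) passed adjusted over the list alone. These 3 passes rest on the variance trend over genes, not on each gene's own spread. The authors' equal-variance test gave p = 0.221 for mt-Atp6 and p = 0.616 for mt-Nd4. Repeat-rich genes held 48.8% and 46.2% of the summed FPKM in Eldr cKO 2 and 3, where mitochondrial shares were lowest. Relative to the genes outside both groups, the mitochondrial sum was instead lowest in Eldr cKO 1 and control 3. The call on the mitochondrial list was lost after quantile normalization (mean -0.32, adjusted p = 0.206) and at a mean of at least 5 FPKM (adjusted p = 0.0584), and the mean of -0.88 became -0.35 without control 1, -0.60 without Eldr cKO 2 and -1.55 without control 3 (adjusted p from 3.40e-28 to 0.206 over the alternative fits). In the neutrophil list 5 of 5 tested genes were higher in Eldr cKO with a median of 1.64 (limma camera, adjusted p = 0.0250, and adjusted p = 0.980 with an estimated correlation), and 0 passed adjusted over the list alone. These were S100a8 at 3.08, 0 and 0 FPKM in the controls against 14.7, 0 and 25.8 FPKM in Eldr cKO, with Lcn2, S100a9, Chil3 and Retnlg. The neutrophil call was lost at pseudocounts of 0.1 (adjusted p = 0.187) and 0.5 (adjusted p = 0.0504), without control 2 (adjusted p = 0.0557), without control 3 (adjusted p = 0.0924) and with the replicate number as a block (adjusted p = 0.0746), with a range from 0.00428 to 0.187 over the alternative fits. Eldr cKO 3 had the highest mean log2(FPKM + 1) over the list (3.49), and without it 3 genes were left above the filter, 2 higher and 1 lower, too few for the list to be tested.

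The lists of cartilage and senescence biology were not called. Among 13 tested cartilage matrix genes, 4 were higher and 9 lower in Eldr cKO, with Fmod, Comp, Cytl1 and Sox9 at the smallest p (median -0.27, camera, adjusted p = 0.954). Of 11 cell cycle inhibitors and regulators, 5 were higher and 6 lower; their median was -0.21 and their mean 0.46, with Cdkn1a, Lmnb1 and Gadd45a on the higher side and Cdkn2d on the lower (camera, adjusted p = 0.617). This mean was 0.084 without Eldr cKO 1, 0.085 without control 2 and 1.06 without Eldr cKO 2. The list holds other genes such as Lmnb1 beside the inhibitors, so its mean does not measure inhibitors alone. Of 19 senescence-associated secretory genes, 9 were higher and 10 lower, led by Ccl8 and Igfbp7 in opposite directions (median -0.04, mean 0.02, camera, adjusted p = 0.866), and 1, Ccl8, passed adjusted over the list alone. Chondrocyte hypertrophy genes were higher in 8 of 10 (median 0.79, mean 0.33, camera, adjusted p = 0.661) and matrix-degrading enzymes in 7 of 11 (median 0.55, camera, adjusted p = 0.785). Without the 5 rows of uncertain identity, among them the row named Ihh, the hypertrophy mean was 0.89 (camera, adjusted p = 0.0575, with a range up to 0.893 over the alternative fits). Hedgehog genes split into 4 higher and 4 lower, with a median of 0.17, a mean of -0.25 (0.375 without the 5 rows) and no call (camera, adjusted p = 0.957). The row named Ihh was the member that passed adjusted over the list alone in the hedgehog and the hypertrophy lists, and the row named Foxo1 was that member in the autophagy list. Among other cell types, macrophage markers were higher in 13 of 19 genes, C1qc having the smallest p (camera, adjusted p = 0.324, and 0.0199 without control 2, with a range up to 0.716 over the alternative fits), and fibroblast matrix genes such as Tagln and Thbs1 were higher in 17 of 23 (camera, adjusted p = 0.324). Lists of lymphocyte, osteoblast and osteoclast markers had fewer than 5 tested genes and were not tested.

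The authors' deposited table gave a p under 0.05 for 249 of 12560 genes, 90 higher and 159 lower in Eldr cKO. By chance alone, 628 genes would be expected under that p. Of the 249, 82 were listed at 0 in all 3 libraries of a group. A q under 0.05 was given in the authors' deposited table for 2 genes. Eva1b was listed at 0 in each control and at 8.09, 9.84 and 9.14 FPKM in Eldr cKO (q = 0.0137 in the authors' deposited table). Apopt1 was listed at 3.34, 4.10 and 4.21 FPKM in the controls and at 0 in each Eldr cKO library (q = 0.0286 in the authors' deposited table). The same genes had an adjusted p of 1.00 in limma. There the SE (1.39 for Eva1b and 1.32 for Apopt1) came from the variance trend over genes, not from the spread of these values. For comparison, 1 fragment on a 2 kb transcript was worth 2.61, 9.55 and 8.93 FPKM in Eldr cKO 1, 2 and 3.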

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

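Leaving out the 2 deepest libraries, leaving out the 5 rows out of gene ID order and scaling to the total of other genes were chosen after seeing the data. The count of 0 genes changed (135 at an unadjusted p under 0.05) held under other pseudocounts, filters and scalings, robust estimation, adjusted p under 0.1 and the replicate block. It became 6 with library quality weights (Gm10800 and Gm21738 higher, Atp5k, Atpif1, mt-Atp6 and Ndufa1 lower in Eldr cKO), 2 with the 2 deepest libraries left out (Gm10800 and Gm21738), and 0 to 4 with each library left out. Unadjusted counts were 65 at a minimum of 5 FPKM, 223 with the replicate block, 237 with the replicate block and quantile normalization, 440 with quality weights, 219 without the 2 deepest libraries and 377 without Eldr cKO 1. The share of higher genes was 30.4% among the 135, 13.1% (without control 2) to 69.7% (without Eldr cKO 2) with each library left out, and 40.6% after quantile normalization, which moved the median of all genes from -0.13 to 0.01. The 2 lists called became 1 with a pseudocount of 0.1 or 0.5, 1 with quantile normalization, 1 with the replicate block (mitochondrial), 4 with the 2 deepest libraries left out, 1 to 7 with each library left out, and 0 at a minimum of 5 FPKM, with estimated correlation or with fry. Too few genes for a test were left in the neutrophil list without Eldr cKO 3 and in this and other lists at a minimum of 5 FPKM. The 7 without control 3 were histones, mitosis and ribosomal proteins higher and the mitochondrial genome, oxidative phosphorylation, skeletal muscle and synovial fibroblast lists lower in Eldr cKO. The 2 genes with a q under 0.05 in the authors' deposited table both kept a fold of at least 2. The replicate numbers were not taken to pair the libraries, since deviations from the group means correlated at 0.284, 0.152 and 0.0954 for numbers 1, 2 and 3, although each control correlated best with its own number. Uncalled values that reversed were, with quality weights, Col10a1 (-0.29), Egfr (-0.20) and the hypertrophy (-0.15), matrix degradation (-0.16) and secretory (-0.26) list means. With the 2 deepest libraries left out, Kat6a was -0.053, Prg4 0.82 and the secretory mean -0.34. The secretory mean was -0.13 and -0.023 at pseudocounts of 0.1 and 0.5 and -0.18 at a minimum of 5 FPKM, the matrix degradation mean -0.17 at a pseudocount of 0.1, and the hedgehog mean 0.375 without the 5 rows. With each library left out, ranges were -0.11 to 0.84 for Egfr, -0.50 to 0.75 for Kat6a, -1.39 to 3.47 for mt-Nd4, -1.76 to 0.30 for Prg4, -0.73 to 0.30 for cartilage matrix, -0.85 to 0.034 for hedgehog, -0.19 to 0.73 for hypertrophy, -0.17 to 0.35 for matrix degradation and -0.27 to 0.34 for secretory genes. The cause was not tested, apart from the hedgehog mean, where the row named Ihh was removed. Of the 30 named genes tested, 6 turned direction without 1 of the libraries, Adamts4 (-0.24 to 1.13) and Col10a1 (-0.63 to 1.23) included, and 9 more moved by over 1.5 times. These were Cdkn1a, Ndufa1, mt-Atp6, Hspe1, Igfbp7, U2af1, Sox9 (0.015 to 1.43), Ptch1 (0.253 to 1.46) and Hnrnpl (0.255 to 1.11). Of the 30, 5 fell under the filter in 1 such fit, where the difference of means had no test. Over fold changes and list means, wherever tested, 655 values kept their direction and side of the threshold, 29 reversed, 7 gained a call and 7 lost it, and of the counts 42 stayed within 1.5 times and 20 moved further. Count alternatives were not run, since the table held FPKM. In simulation at 10 times the depth limma recovered 52.5% of 4-fold changes.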

Other observations

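The tests of the heart muscle, row order and mitochondrial patterns and the counts over other splits were chosen after the results they bear on had been seen. Histone transcripts stood out in 1 library of each genotype. Over 27 histone genes, most of them replication-dependent, the mean log2(FPKM + 1) was 4.79 in control 3 and 5.13 in Eldr cKO 1, against 2.06 and 0.93 in control 1 and 2 and 0.38 and 1.45 in Eldr cKO 2 and 3. Hist1h3b, a histone H3 gene, was listed at 186 FPKM in control 3 and 137 FPKM in Eldr cKO 1, at 8.01 and 5.17 FPKM in the other controls and at 0 in the other Eldr cKO libraries. Genes of G2 and mitosis had means of 2.44 and 2.14 in control 3 and Eldr cKO 1 and of at most 0.95 in the others. As a share of the summed FPKM of genes outside the mitochondrial and repeat-rich groups, they held 0.174% in control 3. Their share was 0.104% in Eldr cKO 1 and 0.105% in Eldr cKO 3. Genes of S phase held 0.162%, 0.0734% and 0.145% in the same libraries. By share, Eldr cKO 1 did not stand out from Eldr cKO 3 for these lists. The histone list was not called between genotypes (limma camera, adjusted p = 0.955), but it was called higher in Eldr cKO without control 3 (adjusted p = 0.00885) and lower without Eldr cKO 1 (adjusted p = 0.00657), with a range from 0.00359 to 0.998 over the alternative fits.

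Blood and vessel genes were present in both genotypes. Hba-a1, an alpha globin of red cells, was listed at 220, 72.0 and 104 FPKM in the controls and at 146, 153 and 139 FPKM in Eldr cKO. The endothelial and pericyte list had a mean log2(FPKM + 1) of 3.29 in control 1 and 2.80 in Eldr cKO 1, the deepest libraries, and of at most 0.99 in the others. Of 393 olfactory and vomeronasal receptor genes, 65, 149 and 248 were above 0 in control 1, 2 and 3 and 21, 214 and 200 in Eldr cKO 1, 2 and 3. The ratio of mt-Nd6, which lies on the other strand of the mitochondrial genome, to mt-Nd5 was 1.23, 4.08 and 4.94 in the controls and 0.821, 14.4 and 6.23 in Eldr cKO.

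Heart muscle transcripts were abundant in all 6 libraries labelled chondrocytes. Skeletal muscle carried over with joint tissue is argued against as the whole source, since the heart-restricted genes summed to at least 29.6% of the FPKM of genes shared by heart and slow skeletal muscle in each library. Stray heart reads on top of chondrocyte RNA cannot be told apart from a source without chondrocytes. Only 35.7% of the core cartilage genes had a row, and Col2a1 and Acan were not among them. Those with a row reached at most 11.2 FPKM (Comp in Eldr cKO 1). Rows as low as a group mean log2(FPKM + 1) of 0.441 were kept. The genes without a row may therefore have been low, but the rule for keeping rows is not given. The order of 26 heart genes was similar in every pair of libraries (lowest Spearman rho across genes 0.82). These genes range from Mb (at least 406 FPKM) to Tbx5 (at most 5.31 FPKM). Heart material from 1 source or from several would give such an order, so it does not show a common source. Whether the transcripts came from carried-over tissue, exchanged samples or reads of a heart library stays open. No biological explanation was tested, since the genes were abundant in both genotypes.

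The rows named Hpip, Foxo1, Ihh, Errγ and Itgbl1 broke the gene ID order of the table. All 5 had an irregular annotation field (no ID version, a stray space, a non-ASCII symbol, a position off the annotated gene or the opposite strand), against 1 of the 12555 rows in order (two-sided Fisher's exact test, p = 2.31e-18). These kinds of irregularity were chosen after the 5 rows had been seen, so this p-value is not independent support. Annotation fields filled in apart from the rest of the table would give such rows. Positions from a newer annotation of the same genes cannot be told apart from that, because none was used here. The opposite strand of the 2 rows named Ihh and Itgbl1 does not show where their positions came from, and no biological explanation was tested.

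Mitochondrial genome transcripts were lower in Eldr cKO in 12 of 13 genes. Scaling to the total of other genes left a mean log2 fold change of -0.804, against -0.88 for the values as deposited. That total leaves out mitochondrial as well as repeat-rich genes, so on average over the list mitochondrial transcripts were lower relative to the other genes. By summed FPKM the groups overlapped. Mitochondrial transcripts and other genes held 41.1% and 45.5% in control 3. They held 33.9% and 17.3% in Eldr cKO 2, and 33.8% and 20.0% in Eldr cKO 3. In Eldr cKO 1 the shares were 43.6% and 52.6%, with mitochondrial transcripts lower relative to other genes than in each control. The scaling does not take out the repeat-rich share alone, so how much that share contributes through the denominator of FPKM was not tested. Quantile normalization, which reshapes the values of each library rather than applying 1 factor, left -0.32. A shift of each library shared by its mitochondrial transcripts may account for the call, since the adjusted p was 0.98 once the correlation between genes was estimated from the data. The genotype stays open as a source of that shift and was not separable from the libraries.

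Other splits of the 6 libraries into 3 and 3 cannot give a share under 0.05, since there are 10. The real split gave 0 genes changed, which all 10 reach by construction, so that this count tests nothing; the highest other was 5. As many genes at an unadjusted p under 0.05 (135) came from 9 splits. The highest other, 1748, came from control 1, control 3 and Eldr cKO 1 against the rest. These are the deepest libraries, with 20.9%, 37.6% and 26.4% of genes listed at 0. In control 2, Eldr cKO 2 and Eldr cKO 3 it was 62.4%, 63.4% and 60.9%. That count cannot separate depth from other differences between the samples. As many lists called (2) came from 8 splits, with 9 as the highest other.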
